A study of Arabidopsis thaliana with 16 samples.

How the data were processed

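RNA from Arabidopsis floral tissue of the Landsberg erecta background was measured on 16 custom Agilent 2-colour arrays of 45210 features, of which 43793 are not controls. Per the labels' protocols the plants were about 4 weeks old, 20 to 25 plants were pooled for each sample, 500 ng of total RNA was labelled with Cy3 or Cy5, and 10 µM dexamethasone was used for floral induction. The groups are day 0, day 2.5 and day 5 of the ag-1 series and the amiRNA experiment, with 4 arrays each. Replicates are biological replicates by their labels, and each array was turned so that its ratio is homozygous over heterozygous or induced over uninduced. The amiRNA labels differ on time. They give 0 days on replicates 1 and 3, whose induced sample was in Cy3, and 1 day on replicates 2 and 4, where it was in Cy5. Replicate 1 also has 24 hours. The time label thus moves together with the dye orientation, and whether it describes 1 channel or the whole array is not known. The time since induction is therefore not stated here. Day 0 tissue was not treated with dexamethasone, so that day and treatment move together across days, but not between the 2 channels of an array.

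The deposited table gives, for each probe and array, the log10 ratio of Cy5 over Cy3 after background subtraction and dye normalization in Agilent Feature Extraction. Values that the software sets to 0 are kept at 0. Between 18.7% and 26.7% of each column were 0, a share that may also hold small ratios rounded to 0. The table differs from the log ratio in the scanner files by at most 0.005 log10 units. Per the file headers, the scanner files give the median pixel intensity of each spot and of its local background, the processed signals and marks for spots that are well above background, saturated or outliers. The version of Feature Extraction is 10.5.1.1 per the file headers and 9.5.3.1 per the submitters' processing notes. The fits use the median intensities. The plan named the mean signal, for which the files have no column.

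Intensities were corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, with jsonlite 2.0.0 and data.table (1.17.8) for reading. Log2 ratios were normalised by loess within each array with control spots at weight 0. Spots marked as outliers were left out, and repeated spots of a probe were averaged. Probes name a locus in 36953 cases, for 28327 loci, of which 27785 were found in the reference list of gene names (assembly TAIR10.1). The array annotation gives an older build, so no coordinates are printed and the reference served for names and gene order alone. A probe was kept if it was well above background on all 4 arrays of at least 1 condition of the fit, and the brightest such probe stood for its locus (4940 loci have more than 1 probe), which left 20083 genes for ag-1 and 18089 for the amiRNA. The 6049 intergenic and 633 predicted-gene probes were left out of the comparisons and tested apart.

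The 12 ag-1 arrays were fitted together in limma with 1 coefficient per day and a dye term, and differences between days were tested as contrasts. The amiRNA arrays were fitted alone with an effect and a dye term. Levels in the heterozygous channel were taken after loess and Aquantile scaling and fitted with day and dye. Benjamini-Hochberg adjusted p-values under 0.05 are called, over the genes of each comparison, and 9 comparisons were made. Gene lists (20 of them, in each of 4 comparisons) were tested with camera in limma at a preset correlation of 0.01 and, as an alternative, with an estimated one, adjusted over the lists of a comparison. The members adjusted over the list alone are counted beside those adjusted over all genes. Enrichment in the span around AG, which was drawn from the day 0 calls, at day 2.5, at day 5 and with the amiRNA, and the overlap of calls were tested with two-sided Fisher exact tests. Figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and NumPy 2.4.6 under Python 3.11.15.

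Comparisons, tests, gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The rule names the measured anchor genes of the AG network, for each of the 4 main comparisons the 8 highest and 8 lowest called genes with a symbol and with all 4 arrays on the same side, up to 4 called members of each list by lowest adjusted p, and 5 highest and 5 lowest for day differences and heterozygous levels; genes named once may appear in other comparisons. DAD1 was not measured in any fit, and STK was not measured in the amiRNA fit. Lists never called, with their lowest adjusted p over the 4 comparisons, were perianth regulators (0.554), meristem regulators (0.171), organ polarity regulators (0.197), trichome genes (0.112), gibberellin metabolism genes (0.321), cytokinin response genes (0.27), heat shock genes (0.289) and circadian clock genes (0.106). Of 80 list tests 18 were called with the preset correlation, each with mean, median and test of one sign, and 0 with an estimated correlation. In 16 of the 62 tests without a call, mean, median and test were not of one sign.

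The pipeline was tested on simulated data, with independent normal noise for each gene and array at the fitted variance. This noise held no outlying arrays, slide effects or correlation between genes, so recovery in the real data may be lower. At 19714 genes, changes of 0.5 log2 units were recovered in 95.5%, 86.6% and 97.0% of cases at day 0, day 2.5 and day 5, and changes of 1 in 100% at each day. For the difference between day 5 and day 0 the shares were 67.2% and 97.0%, for the amiRNA (17856 genes) 100% for both sizes, and for the heterozygous level at day 5 (19715 genes) 35.8% and 91.0%. Among the unchanged genes 13, 12 and 9 were called at the 3 days, 7 for the difference between day 5 and day 0, 19 for the amiRNA and 7 for the heterozygous level. A list shifted by 0.5 was called at day 5, and so was 1 of the other lists. Alternatives covered background correction, scaling, the deposited table, filters, probe choice, the dye term, array weights, slides, replicate numbers, the arrays in a fit, each left-out replicate and the genes of the span around AG. The arrays are spread over 6 slides and 5 scan batches. Called genes had the same direction within each slide in 41 of 41 cases on both slides of day 0, in 38 of 38 on both slides of day 2.5, in 210 and 212 of 212 at day 5, and in 237 and 232 of 237 for the amiRNA, whose second slide holds 1 array. A result for 1 gene of the amiRNA comparison is not reported here.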

Results

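The series measured messenger RNA in Arabidopsis floral tissue in which the function of AGAMOUS was lowered. AGAMOUS (AG) encodes a MADS-domain transcription factor that specifies stamens and carpels. RNA from 2 conditions was hybridised together on each of 16 2-colour arrays, so every array gives a ratio within itself. Of these arrays, 12 compare plants homozygous for the loss-of-function allele ag-1 with their heterozygous siblings, at day 0, day 2.5 and day 5 of a synchronised floral induction, with 4 arrays for each day. These plants carry a steroid-inducible form of the floral regulator AP1 in an ap1 cal background and form inflorescence-like meristems until dexamethasone starts flowers in step. Day 0 is untreated tissue, and day 5 corresponds to young flowers in which the inner organs are beginning to form. The remaining 4 arrays compare inflorescences with and without induction of an artificial microRNA (amiRNA) against AG.

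Each replicate was a separate pool of about 20 to 25 plants, and the dye of the 2 conditions was exchanged between replicates. Between 55.0% and 65.9% of the probes were well above background in the homozygous or induced channel of an array, and between 55.0% and 66.4% in the other channel. No spot was saturated. The number of arrays limits the precision. The p-values rest on the spread between replicate arrays, which joins differences between pools of plants with those of arrays and slides. In ag-1 this spread is pooled over the 3 days, so it is not that of a single day. All changes below are log2 fold changes estimated over 4 arrays unless another n is given, homozygous over heterozygous or induced over uninduced, with the standard error (SE) of the fit.

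The day 0 comparison asks how the homozygous tissue differs from the heterozygous tissue before flowers are initiated. AG itself was lower by a log2 change of -0.60 (SE 0.08, n = 4, adjusted p = 0.00967). The strongest falls among genes with a symbol were EDR2, a negative regulator of disease-related cell death, at -1.99 (SE 0.22, adjusted p = 0.00221), and UNE16, which encodes a MYB-like protein, at -1.44 (SE 0.20, adjusted p = 0.011). SBP2, which encodes a selenium-binding protein, followed at -0.92 (SE 0.10, adjusted p = 0.0015). The strongest rise was VPS54, which encodes a vesicle-tethering protein, at 1.24 (SE 0.18, adjusted p = 0.0118) on one of its 2 probes, while the other had -0.00. SPL, which starts sporogenous tissue, had a value of -0.02 (SE 0.25, adjusted p = 1). SUP, a zinc finger gene of the stamen and carpel boundary, had one of -0.05 (SE 0.11, adjusted p = 1) and WUS, which maintains stem cells, of -0.04 (SE 0.05, adjusted p = 1). AP3, a gene of petal and stamen identity, had a value of -0.41 (SE 0.08, adjusted p = 0.111) and STK, an ovule MADS-box gene, of 0.25 (SE 0.05, adjusted p = 0.145), neither of which passed the test.

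Of 20083 genes tested at day 0, 15 rose and 26 fell, and all 41 lie on chromosome 4. They fall between AT4G13640 and AT4G19650, a span of 885 genes of the reference that contains AG. From its start to AG there are 787 genes, and from AG to its end 97. Within this span 41 of 521 tested genes were called, against 0 of 19562 elsewhere (limma, with 431 genes at an unadjusted p under 0.05 over all genes). The span was drawn after the calls were seen, from the first to the last of them, so no test of its share is given for day 0. Other members that rose include CYCT1;2, a cyclin gene, at 0.80 (SE 0.12, adjusted p = 0.0172), and SHM4, of serine and glycine metabolism, at 0.76 (SE 0.13, adjusted p = 0.0394). HPL1, a hydroperoxide lyase gene, rose by 0.72 (SE 0.12, adjusted p = 0.0394) and PUP7, of the purine permease family, by 0.71 (SE 0.10, adjusted p = 0.0137). Smaller rises were found for UMAMIT2, a transporter gene, at 0.49 and HB-2, a homeodomain gene of shade responses, at 0.44. BEH3, a relative of the brassinosteroid regulator BES1, rose by 0.43 and TCP2, a regulator of leaf growth, by 0.38 on one of its 4 probes, of which the lowest had -0.13. With the mean over probes TCP2 had 0.13 (adjusted p = 1). NLM1, an aquaporin gene, fell by 0.75 on the log2 scale and CMT2, a DNA methyltransferase gene, fell by 0.47.

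Among the 20 gene lists, 5 were called at day 0. The 15 measured jasmonate genes lay below 0 without exception, with a mean of -0.23 (SD 0.15, camera adjusted p = 2.47e-10, and adjusted p = 0.0985 with an estimated correlation). None of them passed the test on its own. LOX3 had a value of -0.50 and JAZ5 of -0.46. The 20 photosynthesis genes had a mean of -0.08 (SD 0.05, adjusted p = 6.13e-05, and adjusted p = 0.27 with an estimated correlation). The 8 leaf TCP genes had a mean of 0.08 (SD 0.12, adjusted p = 0.00184, and adjusted p = 0.374 with an estimated correlation). TCP2, the member that rose, lies in the span around AG. The 20 carpel and ovule regulators had a mean of 0.03 (adjusted p = 0.00719, and adjusted p = 0.457 with an estimated correlation). For the 8 auxin synthesis and transport genes it was a mean of 0.06 (adjusted p = 0.00719, and adjusted p = 0.27 with an estimated correlation). With median centring in place of loess the carpel and ovule mean was -0.01 and the auxin mean -0.03. The median of all genes was -0.09 in that setting. Adjusted over the list alone, 1 leaf TCP gene and 1 carpel and ovule gene were called, and none of the jasmonate, photosynthesis or auxin genes.

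The day 0 count fell to 17, 19 and 12 without replicates 1, 2 and 3, and stood at 34 without replicate 4. With slide as a fixed block, an alternative chosen after the data were seen, 15 genes were called. Of 18 alternatives, EDR2 and SBP2 kept their calls in 18, BEH3 in 15, AG, VPS54 and CYCT1;2 in 13, UNE16 in 12, PUP7, TCP2 and UMAMIT2 in 11, HPL1 in 9, SHM4 and CMT2 in 8, and HB-2 and NLM1 in 6. Among these named genes every call but those of EDR2 and SBP2 was lost with median centring, which left 13 of the 41, and without replicate 3. The carpel and ovule call was lost without replicate 2 (adjusted p = 0.214) or 4 (0.174), over a range of 0.000201 to 0.457 for its alternatives. So was the auxin call without replicate 2 (0.102) or 4 (0.174), over a range of 0.00284 to 0.27. The leaf TCP call ended without replicate 4 (0.241), over a range of 0.000269 to 0.374, and the photosynthesis call without replicate 3 (0.0563), over a range of 2.02e-06 to 0.27.

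**Figure D1:**
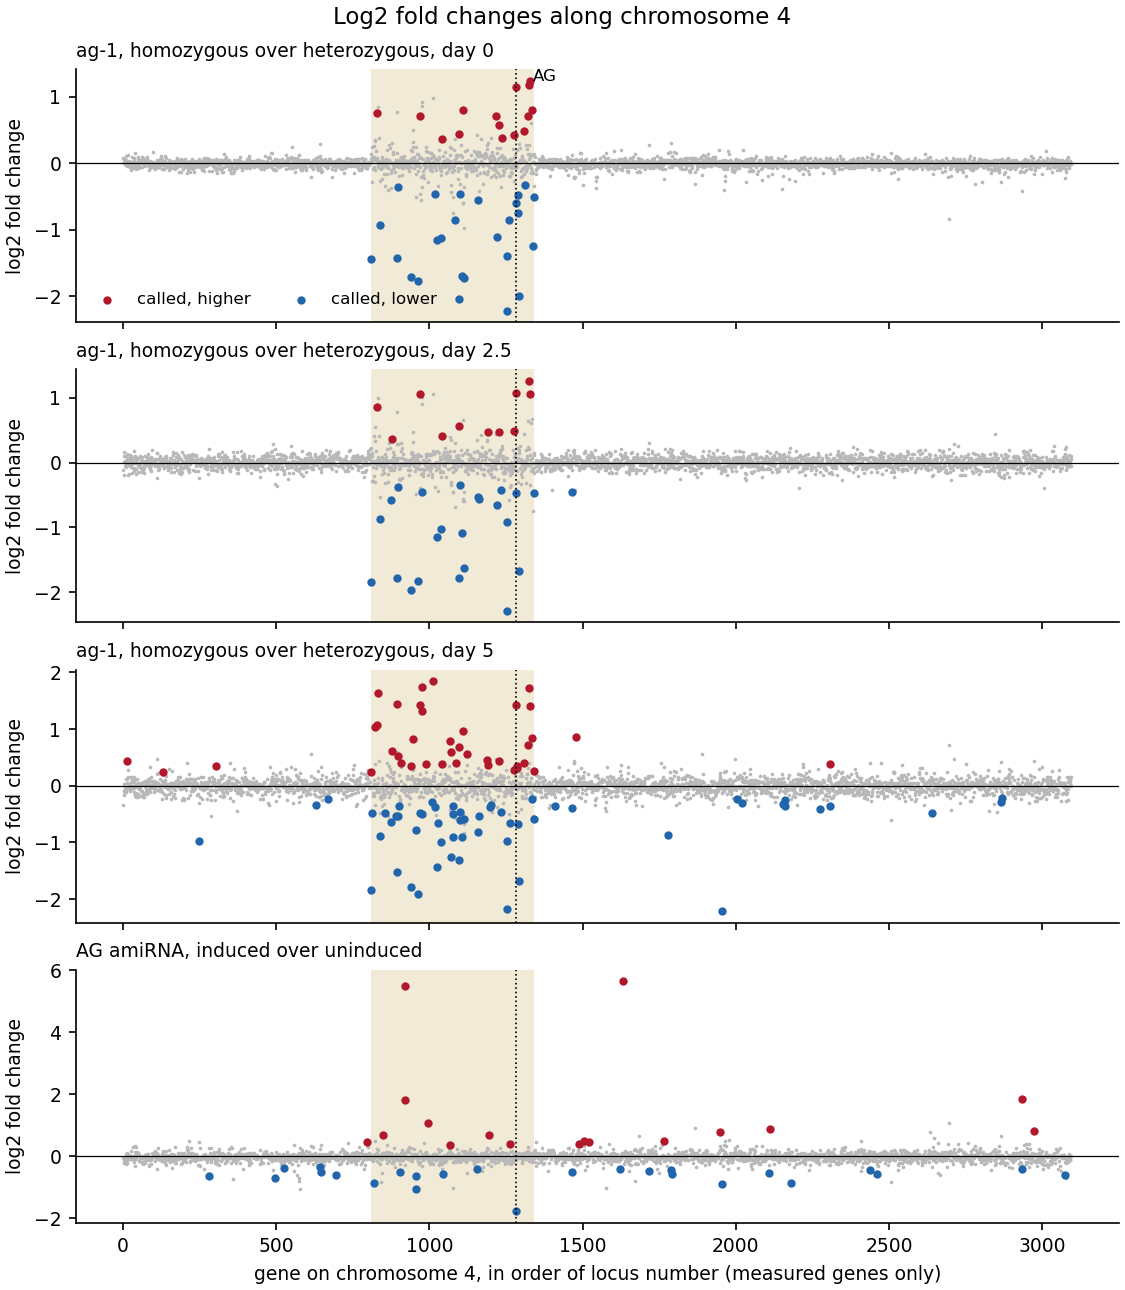
Log2 fold change (vertical axis, log2 units) of each measured gene of chromosome 4 in order of locus number (horizontal axis), in the 3 ag-1 comparisons and with the AG amiRNA. Red and blue points are genes with an adjusted p under 0.05, the shaded band is the span from the first to the last gene called at day 0, and the dotted line marks AG; the called genes of day 0 all fall in the band, and those of the amiRNA lie along the whole chromosome.

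The day 2.5 comparison covers flowers that have just been initiated. Outside the span around AG, 4 genes fell and none rose. REM22, a B3-domain gene of the REM family, was lower by a log2 change of -1.50 (SE 0.08, n = 4, adjusted p = 8.71e-06), or 2.83-fold. SUP was lower by -1.05 (SE 0.11, adjusted p = 0.00209) and ENDO3, an endonuclease gene, by -0.46 (SE 0.05, adjusted p = 0.00209). The fourth gene, AT5G57720, at -0.85 (SE 0.12, adjusted p = 0.0155), was named only after its values were seen. CRC, a YABBY gene of carpel and nectary development, had a value of -1.35 (SE 0.26, adjusted p = 0.0985) and did not pass the test.

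At this stage 11 of 20083 genes rose and 27 fell, and 34 of the 38 lie in the span around AG (Fisher exact p = 2.74e-50). The span was drawn from day 0 calls of the same fit, and the test takes neighbouring genes as independent. This p-value is therefore a description and not independent support. AG had a change of -0.47 (SE 0.08, adjusted p = 0.0486), and this call was lost in 12 of 18 alternatives, among them the removal of any single replicate of day 2.5. Further probes of AG had means of -0.67 (SD 0.09) and -0.44 (SD 0.07) at this day. Of the 41 genes called at day 0, 28 were called again in the same direction, among them UNE16 at -1.84, EDR2 at -1.67, SBP2 at -0.88, VPS54 at 1.06, HPL1 at 1.05, SHM4 at 0.86, HB-2 at 0.56 and BEH3 at 0.48. Genes of the span that were named at this day and not at day 0 are MYC4, a jasmonate-responsive transcription factor gene, at 0.47 (SE 0.06, adjusted p = 0.00351) and PHYD, a phytochrome gene, at 0.42 (SE 0.05, adjusted p = 0.00353). PHYD was also called at day 0, at 0.36. The others are HCD1 at 0.37 (SE 0.06, adjusted p = 0.0387) and RAB1C, which encodes a small GTPase, at -0.56 (SE 0.07, adjusted p = 0.00559). No list was called at day 2.5 by camera. The lowest adjusted p was 0.133, for the genes that the literature places downstream of AG and for the jasmonate genes, whose mean was 0.11. The 10 measured members of the downstream list had a mean of -0.26 (SD 0.51), with 1 of them called and 2 adjusted over the list alone. The count was 23 without replicate 3 and 21 without replicate 4. The arrays share slides, and with slide as a fixed block 1 gene was still called, REM22 (adjusted p = 0.0306). The calls of SUP (-1.01, adjusted p = 0.682), ENDO3 (-0.45, adjusted p = 0.82), UNE16 (-1.80, adjusted p = 0.564), HPL1 (0.95, adjusted p = 0.257) and the others were lost. Over all alternatives REM22 kept its call in 19 of 19 and ENDO3 in 16 of 19, and of 18 SUP, UNE16 and SBP2 kept theirs in 17, HPL1 in 16, PHYD and HB-2 in 15, RAB1C, MYC4, BEH3 and EDR2 in 14, VPS54 in 11, SHM4 in 10 and HCD1 in 9. With the mean over its 3 probes MYC4 had a value of 0.20 and was not called.

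The day 5 comparison covers young flowers in which stamen and carpel primordia form. REM22 fell by 3.01 on the log2 scale (SE 0.08, n = 4, adjusted p = 2.72e-09), an 8.07-fold difference. CRC fell by 2.35 (SE 0.26, adjusted p = 0.000917) and SPL fell by 2.21 (SE 0.25, adjusted p = 0.00111), which is 5.11-fold and 4.63-fold. WOX12, a homeodomain gene, fell by 1.57 (SE 0.09, adjusted p = 8.41e-06) and SUP fell by 1.06 (SE 0.11, adjusted p = 0.000729). GA3OX3, which encodes an enzyme of the last step to active gibberellins, rose by 0.85 (SE 0.08, adjusted p = 0.000463).

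Of the 10 measured genes that the literature places downstream of AG, 6 fell and none rose, and SPL, CRC and SUP are among the 6. The others are VDD (a B3-domain gene of the embryo sac, -0.71, SE 0.10, adjusted p = 0.00405), SHP2 (a carpel MADS-box gene, -0.50, SE 0.10, adjusted p = 0.0311) and KNU (a repressor of WUS, -0.45, SE 0.09, adjusted p = 0.0434). The list had a mean of -0.78 (SD 0.85, camera adjusted p = 1.38e-09, and adjusted p = 0.103 with an estimated correlation). In it 8 members were called when adjusted over the list alone. SHP1, a close relative of SHP2, had a value of -0.32 (adjusted p = 0.165), GA3OX1 of -0.27 (adjusted p = 0.132) and STK of 0.02 (adjusted p = 0.892).

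Of 20 carpel and ovule regulators, 5 fell and none rose, CRC, VDD and SHP2 among them. The others are HEC2 (a gene of transmitting tract and style development, -0.87, SE 0.16, adjusted p = 0.0234) and STY1 (a style regulator, -0.54, SE 0.10, adjusted p = 0.0196). Their mean was -0.30 (SD 0.55, adjusted p = 0.000103, and adjusted p = 0.367 with an estimated correlation), with 8 called when adjusted over the list alone. Of 13 early anther regulators 2 fell, SPL and NUB (a zinc finger gene that acts with JAG in organ growth, -0.69, SE 0.12, adjusted p = 0.0134). The list had a mean of -0.33 (SD 0.59, adjusted p = 0.000156, and adjusted p = 0.295 with an estimated correlation) and 3 called when adjusted over the list alone. LAP3, a pollen wall gene, fell by 0.78 (SE 0.08, adjusted p = 0.000558) on one of its 2 probes, and the other had -0.05. The calls of SHP2, KNU, HEC2, STY1 and NUB were each lost without replicate 3 or 4 of day 5 and with that day's arrays alone. SHP2 then had an adjusted p of 0.226 and 0.126 without these replicates, KNU of 0.29 and 0.284, HEC2 of 0.197 and 0.127, STY1 of 0.153 in both cases and NUB of 0.127 and 0.122. Values also depend on the signal used, as HEC2 ranged from -3.19 to -0.63 over its alternatives, KNU from -2.04 to -0.34, SHP2 from -1.14 to -0.34 and SPL from -3.42 to -1.48. The 15 mitotic genes lay below 0 without exception, with a mean of -0.17 (SD 0.12, adjusted p = 0.000103, and adjusted p = 0.367 with an estimated correlation), 0 called over all genes and 2 adjusted over the list alone. CYCB1;1, a mitotic cyclin gene, had a value of -0.46 (adjusted p = 0.0605).

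Among 18 meristem regulators, 3 rose and 2 fell, and 9 were called when adjusted over the list alone. STM, which keeps meristem cells undifferentiated, had a change of 0.37 (SE 0.07, adjusted p = 0.0253) and PNF, a partner of STM, of 0.34 (SE 0.06, adjusted p = 0.0167). With median centring in place of loess their values were -0.04 and -0.03, in a setting where the median of all genes was -0.31. TFL1, a gene of inflorescence identity, rose by 0.50 (SE 0.11, adjusted p = 0.0455), and CUC2, an organ boundary gene, fell by 0.56 (SE 0.08, adjusted p = 0.00651). WUS had a value of 0.03 (SE 0.05, adjusted p = 0.809), and the list as a whole was not called (adjusted p = 0.171). In the perianth list TOE3, an AP2-like gene, fell by 0.67 (SE 0.09, adjusted p = 0.00404) and PAN, a bZIP gene of floral organ number, fell by 0.37 (SE 0.08, adjusted p = 0.0464), 2 of 15 members. The TOE3 call was kept in 18 of 19 alternatives and the PAN call in 11 of 19, and PAN lost it without replicate 2, 3 or 4 of day 5. The petal and stamen genes AP3 and PI had values of -0.03 (adjusted p = 0.886) and -0.08 (adjusted p = 0.622). SEP3, a cofactor of the floral MADS proteins, had a change of 0.31 (SE 0.06, adjusted p = 0.0274). With median centring its value was -0.12, which is below 0 but above that median of all genes. The 20 photosynthesis genes had a mean of 0.10 (SD 0.11, adjusted p = 0.00322, and adjusted p = 0.367 with an estimated correlation), and 0 members were called over all genes or adjusted over the list alone. With median centring their mean was -0.26, against -0.31 for the median of all genes.

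AG had a value of -0.28 at day 5 (SE 0.08, adjusted p = 0.144) and was lower in the homozygote on all 4 arrays by its brightest probe. Another of its 3 probes had a mean of -0.46 (SD 0.09) and was also lower on all 4 arrays. The remaining AG probe, with a mean of -0.18, had 0.03 on replicate 2. In the span around AG 34 genes rose and 40 fell, and outside it 27 rose and 111 fell (Fisher exact p = 2.02e-63 for the span against the rest). The limits given for this test at day 2.5 hold here too. The span holds 7 of the 8 strongest named rises, with DI21, a drought-induced gene, at 1.84 (SE 0.27, adjusted p = 0.00485) and RALFL31, of the RALF peptide family, at 1.64 (SE 0.23, adjusted p = 0.00356). MDA1, an organelle gene expression factor, rose by 1.45 (SE 0.21, adjusted p = 0.00406). Further values are HPL1 at 1.42, VPS54 at 1.40, SHM4 at 1.07 and J20, a chaperone gene, at 1.03, with UNE16 at -1.84 and EDR2 at -1.67 among the falls. AGO3, an Argonaute gene elsewhere in the genome, fell by 0.99 (SE 0.20, adjusted p = 0.0351), with a range of -2.06 to -0.65 over its alternatives, and lost its call in 5 of 18, among them without replicate 3 or 4 of day 5. All 41 genes called at day 0 had the same direction at day 5, 31 of them called. Their log2 changes on the 2 days had r = 0.943 across genes, which are not independent replicates.

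With that day's arrays alone 13 genes were called, SUP and VDD not among them, and these 2 kept their calls in 16 of 18 alternatives. Of the other named calls REM22 and WOX12 were kept in 19 of 19 alternatives and UNE16 in 18 of 18, while STM was kept in 12, PNF in 13, CUC2 in 16 and SEP3 in 9 of 19, and DI21 in 15 of 18. No alternatives were run for TFL1 at day 5. In total 61 of 20083 genes rose and 151 fell. The count was 385 without replicate 1, 86 without replicate 3 and 104 without replicate 4, and it was 85 with slide as a fixed block, where CRC (adjusted p = 0.0575), SUP (adjusted p = 0.0555), VDD, STY1, CUC2, STM, PNF, SEP3, PAN and DI21 lost their calls. The photosynthesis call was lost without replicate 2 (adjusted p = 0.214, over a range of 3.49e-05 to 0.367 for its alternatives). Median centring in place of loess moved the median of all genes to -0.31 at day 5 and left 2 rises among 101 calls, while 172 of 368 calls were rises with no background subtraction.

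**Figure D2:**
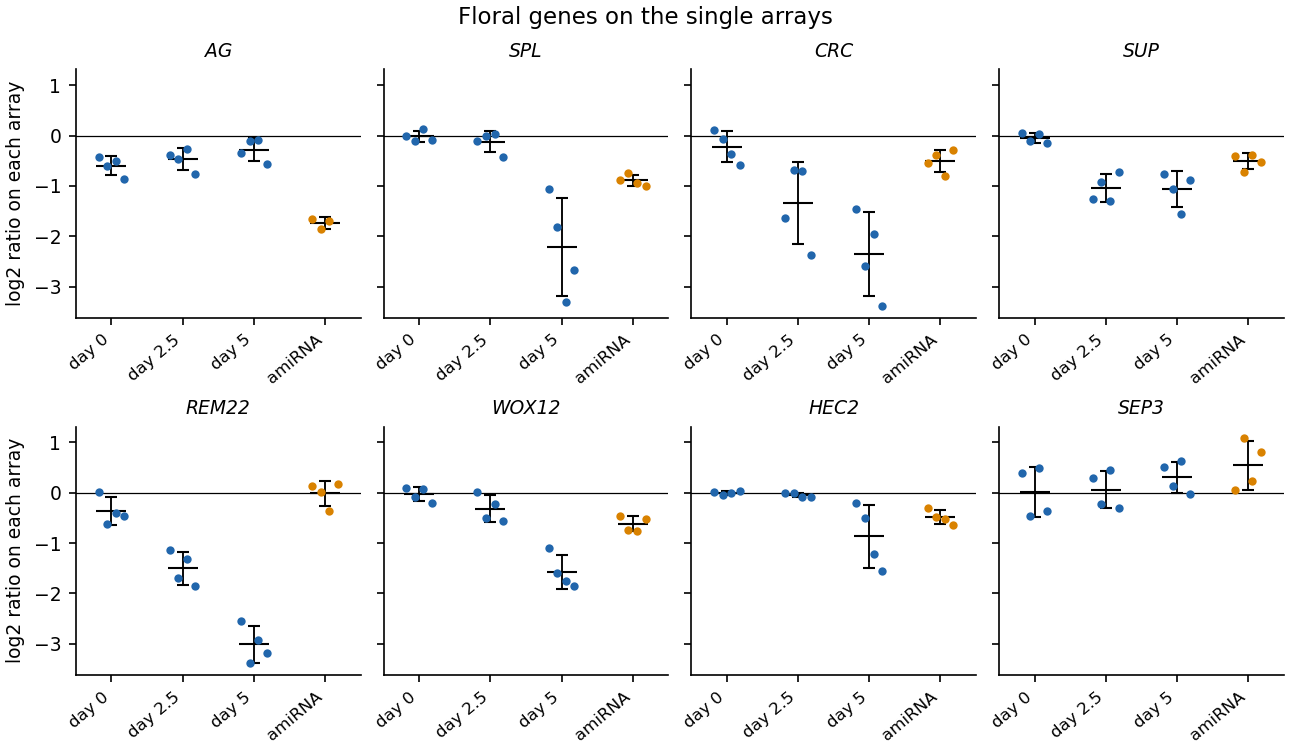
Log2 ratio on each array (vertical axis, log2 units) of 8 floral genes at day 0, day 2.5 and day 5 of the ag-1 series (blue, homozygous over heterozygous) and with the AG amiRNA (orange, induced over uninduced); points are single arrays, left to right replicates 1 to 4, and bars the mean and SD. REM22 lay near -1.50 at day 2.5 and -3.01 at day 5, and CRC, SPL, WOX12 and HEC2 had their lowest values at day 5. SEP3 alternates with the dye orientation, and its day 5 value was negative with median centring, as was the median of all genes (-0.31).

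The differences between days ask whether the effect of ag-1 itself changes over flower development. From day 0 to day 2.5 the effect on REM22 fell by 1.14 on the log2 scale (SE 0.11, adjusted p = 0.00884) and the effect on ENDO3 fell by 0.59 (SE 0.07, adjusted p = 0.0206). From day 0 to day 5 the effect on REM22 fell by 2.65 (SE 0.11, adjusted p = 6.89e-07), and the effect on SPL moved by -2.19 (SE 0.36, adjusted p = 0.0459). It moved by -1.54 for WOX12 (SE 0.13, adjusted p = 0.000487), for IDD12, a zinc finger gene, by -1.05 (SE 0.17, adjusted p = 0.0494) and for AGO5, an Argonaute gene, by -1.04 (SE 0.16, adjusted p = 0.0375). It rose for GA3OX3 by 0.91 (SE 0.12, adjusted p = 0.0141) and for MT2A, a metallothionein gene, by 0.79 (SE 0.11, adjusted p = 0.0251). Rises were also found for GA2OX4, a gibberellin-inactivating enzyme gene, by 0.73 (SE 0.10, adjusted p = 0.0251) and for P5CS1, of proline synthesis, by 0.58 (SE 0.08, adjusted p = 0.0267). From day 2.5 to day 5 it fell for REM22 by 1.51 (SE 0.11, adjusted p = 0.000415) and for WOX12 by 1.25 (SE 0.13, adjusted p = 0.00471). In total 2, 26 and 2 genes were called for the 3 differences, 5 of the 26 as rises, and 1 gene of the span around AG was among the 26. From day 0 to day 5 REM22 and WOX12 kept their calls under 23 of 23 alternatives and GA3OX3 under 16, while GA2OX4 kept it under 12, MT2A and P5CS1 under 11, IDD12 and AGO5 under 10, and SPL under 11 of 22. From day 0 to day 2.5 REM22 kept its call under 10 of 22 and ENDO3 under 6 of 22, neither of them with slide as a fixed block, which also ended the calls of REM22 (adjusted p = 0.281) and WOX12 (adjusted p = 0.0876) from day 2.5 to day 5. Without 1 replicate the second count ranged from 2 to 67. It was 2 without replicate 1 or 4 of day 0, 3 without replicate 2 or 3 of day 0, and 67, 17, 3 and 11 without replicates 1 to 4 of day 5. The first count was 0 without replicate 1, 2 or 4 of day 0 or replicate 2 or 3 of day 2.5 and 1 without replicate 3 of day 0 or replicate 1 of day 2.5. The difference from day 2.5 to day 5 gave 18 without replicate 1 of day 5.

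The heterozygous channel describes the course of flower development in the reference genotype, where stage and dexamethasone move together because day 0 was untreated. AP3 was higher by 6.51 at day 2.5 (SE 0.27, n = 4, adjusted p = 9.42e-08) and by 6.37 at day 5 (SE 0.27, adjusted p = 5.33e-08). REM22 was higher by 5.03 and 6.26 (SE 0.22, adjusted p = 1.01e-07 and 1.8e-08), SEP3 by 4.66 and 4.93 (SE 0.20, adjusted p = 9.63e-08 and 3.54e-08) and AG by 4.49 and 4.68 (SE 0.33, adjusted p = 6.47e-06 and 1.94e-06). FOP1, a petal development gene, rose by 4.38 at day 2.5 (SE 0.20, adjusted p = 2e-07) and LOX2, a jasmonate synthesis gene, rose by 4.68 at day 5 (SE 0.55, adjusted p = 8.47e-05). LSH1 had changes of -4.54 and -5.08 (SE 0.14, adjusted p = 2.54e-08 and 7.5e-09) and FAF3 of -4.20 and -4.98 (SE 0.25, adjusted p = 1.22e-06 and 1.87e-07). Lower too were TFL1 with -3.47 and -3.96 (SE 0.28), LBD19 with -3.08 and -4.15 (SE 0.18) and PUCHI, an early bract and flower regulator, with -2.95 and -3.94 (SE 0.21). Of 20083 genes 1201 were higher and 1259 lower at day 2.5, and 2262 higher and 2515 lower at day 5. Days and slides are partly joined here, and with slide as a fixed block the counts were 899 and 2516. Without replicate 2 of day 0 the first count was 1587. The calls named here were kept in 15 of 15 alternatives, but their sizes depend on the signal used. REM22 ranged from 4.46 to 6.98 at day 2.5 and from 4.94 to 8.14 at day 5, AG from 4.30 to 5.41 and 4.33 to 5.61, FOP1 from 3.89 to 5.76 at day 2.5, LOX2 from 3.81 to 5.68 at day 5 and PUCHI from -5.68 to -3.75 at day 5.

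The amiRNA comparison asks what changes when an amiRNA against AG is induced in inflorescences that have already formed flowers. Its 2 channels differ in the induction treatment as well as in AG, and none of its arrays applies the treatment without the amiRNA. Within these arrays an effect of the treatment itself cannot be told from one of lower AG, for single genes or for gene lists. AG fell by 1.77 on the log2 scale (SE 0.07, n = 3, adjusted p = 0.00121), or 3.41-fold. Its spot on replicate 4 was marked as an outlier by the scanner software and left out, and 2 further probes of AG had means of -0.89 and -1.38 over 4 arrays. The strongest changes were rises. MIR319a, the locus of a microRNA that acts on TCP genes, rose by 5.64 (SE 0.11, n = 4, adjusted p = 7.2e-06) from an uninduced level that was well above background on 2 of the 4 arrays, so that its size depends on the signal used, from 5.31 with median centring to 8.76 with scanner processed signals. The MIR319a probe might also read the amiRNA transgene, which was not tested. NAC1, a transcription factor gene of auxin response, rose by 3.95 (SE 0.12, adjusted p = 8.17e-05), with 1.99 for the mean over its 5 probes, of which the lowest had 0.01, and 5.80 with scanner processed signals. STP1, a sugar transporter gene, rose by 3.12 (SE 0.16, adjusted p = 0.000997). EXPA2, an expansin gene, was at least 18.3-fold higher on the loess scale (adjusted p = 0.000345), as its uninduced level was not well above background on any array. This bound sets the induced level against the higher of the floor and the uninduced signal of each array. It depends on the scale, as the log2 change was 4.19 with loess, 3.93 with median centring and 9.06 with scanner processed signals.

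SPL had a change of -0.89 (SE 0.07, adjusted p = 0.00345), CRC of -0.51 (SE 0.07, adjusted p = 0.0305), SUP of -0.51 (SE 0.06, adjusted p = 0.0212), WUS of -0.51 (SE 0.07, adjusted p = 0.0277) and HEC2 of -0.49 (SE 0.07, adjusted p = 0.0319). Of 9 measured genes placed downstream of AG 3 fell, SPL, CRC and SUP, none rose, and 4 were called when adjusted over the list alone. The list had a mean of -0.30 (SD 0.29, camera adjusted p = 0.000532, and adjusted p = 0.458 with an estimated correlation). SHP1 had a value of -0.06 (adjusted p = 0.752), KNU of -0.10 (adjusted p = 0.405) and SHP2 of -0.05 (adjusted p = 0.898). The SHP2 value depended on single arrays, with -0.34 without replicate 2 and 0.23 without replicate 4. SEP3 rose by 0.55 (SE 0.07, adjusted p = 0.0287) on its brightest probe, while the lowest of its 4 probes had -0.08. The SPL call was kept under 16 of 16 alternatives. Those of CRC, SUP, WUS, HEC2 and SEP3 were lost with scanner processed signals, with the deposited table, with median centring and without replicate 1 or 3, with a highest adjusted p of 0.372, 0.201, 0.235, 0.204 and 0.575.

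The 13 tapetum and pollen wall genes lay below 0 without exception, with a mean of -0.75 (SD 0.40, adjusted p = 6.22e-08, and adjusted p = 0.458 with an estimated correlation). LAP3 fell by 1.64 (SE 0.06, adjusted p = 0.000264), with -0.01 on its other probe, and 11 were called when adjusted over the list alone. The early anther list was not called (adjusted p = 0.289), and in it TDF1, a tapetum MYB gene, fell by 0.78 (SE 0.09, adjusted p = 0.0174). The 7 pollen genes lay above 0 without exception, with a mean of 0.33 (SD 0.18, adjusted p = 0.000141, and adjusted p = 0.516 with an estimated correlation), 0 called over all genes and 4 adjusted over the list alone. Their mean was 0.20 on the 3 arrays of one slide and 0.74 on replicate 4, the single array of the other, and the tapetum means were -0.77 and -0.69.

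The 9 flavonoid genes had a mean of -0.47 (SD 0.39, adjusted p = 4.27e-05, and adjusted p = 0.516 with an estimated correlation), 1 called over all genes and 6 adjusted over the list alone. TT7, flavonoid 3-prime hydroxylase, fell by 1.15 (SE 0.10, adjusted p = 0.00654). Outside the list UF3GT, an anthocyanin glycosyltransferase gene, fell by 1.37 (SE 0.20, adjusted p = 0.0419) and GSTF12, of anthocyanin transport, fell by 1.09 (SE 0.17, adjusted p = 0.048). The 13 jasmonate genes had a mean of -0.29 (SD 0.17, adjusted p = 6.97e-06, and adjusted p = 0.458 with an estimated correlation), with VSP1 at -0.46 (SE 0.06, adjusted p = 0.0224) as the member called over all genes and 10 called when adjusted over the list alone. Of 13 touch and wound response genes 3 fell, with CBF3, a cold response regulator, at -0.58 (SE 0.05, adjusted p = 0.0101). The others are its relative CBF2 at -0.45 (SE 0.06, adjusted p = 0.0368) and ERF5, an ethylene response factor gene, at -0.44 (SE 0.06, adjusted p = 0.0319). The list had a mean of -0.27 (SD 0.27, adjusted p = 4.27e-05, and adjusted p = 0.458 with an estimated correlation) and 10 called when adjusted over the list alone.

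Photosynthesis genes had a mean of -0.12 over 19 (SD 0.11, adjusted p = 0.00562, and adjusted p = 0.516 with an estimated correlation), with 0 called over all genes and 1 adjusted over the list alone. The 15 mitotic genes had a mean of 0.07 (SD 0.09, adjusted p = 0.0149, and adjusted p = 0.516 with an estimated correlation), with 0 called either way. With median centring their mean was -0.29, near the median of all genes of -0.28 in that setting. WOX14, a homeodomain gene, also rose, at 1.73 (SE 0.12, adjusted p = 0.00336). Rises were smaller for the monooxygenase gene FMO at 1.45 (SE 0.10, adjusted p = 0.00336) and ALPHA DOX2, a fatty acid dioxygenase gene, at 1.44 (SE 0.08, adjusted p = 0.00121). Further falls are FMO GS-OX3, of glucosinolate modification, at -1.36 (SE 0.10, adjusted p = 0.00336) and GSTF6, a glutathione transferase gene, at -1.12 (SE 0.14, adjusted p = 0.0254). Also lower were BAM5, a beta-amylase gene, at -1.05 (SE 0.06, adjusted p = 0.00172), CB5-C, a cytochrome b5 gene, at -0.94 (SE 0.14, adjusted p = 0.0411) and GI, a clock gene, at -0.50 (SE 0.07, adjusted p = 0.0319). Of the named amiRNA calls not yet weighed, CBF3 kept its own in 13 of 16 alternatives, UF3GT, GSTF6, GI, TDF1 and VSP1 in 11, CB5-C and ERF5 in 10, and CBF2 and GSTF12 in 9. Each of these was lost without replicate 1 or 3, while LAP3, TT7, STP1, WOX14, FMO, ALPHA DOX2 and FMO GS-OX3 kept theirs in 16 of 16 and BAM5 in 15 of 15. In all 100 of 18089 genes rose and 137 fell, and 14 of them lie in the span around AG, among 472 tested there (Fisher exact p = 0.00571). The count was 56 without replicate 1, 1020 without replicate 2, 51 without replicate 3 and 2531 without replicate 4. The mitotic call was lost without replicate 3 or 4 (adjusted p = 0.121 in each case, over a range of 0.0047 to 0.516 for its alternatives) and the photosynthesis call without replicate 4 (adjusted p = 0.18, over a range of 0.000158 to 0.516).

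**Figure D3:**
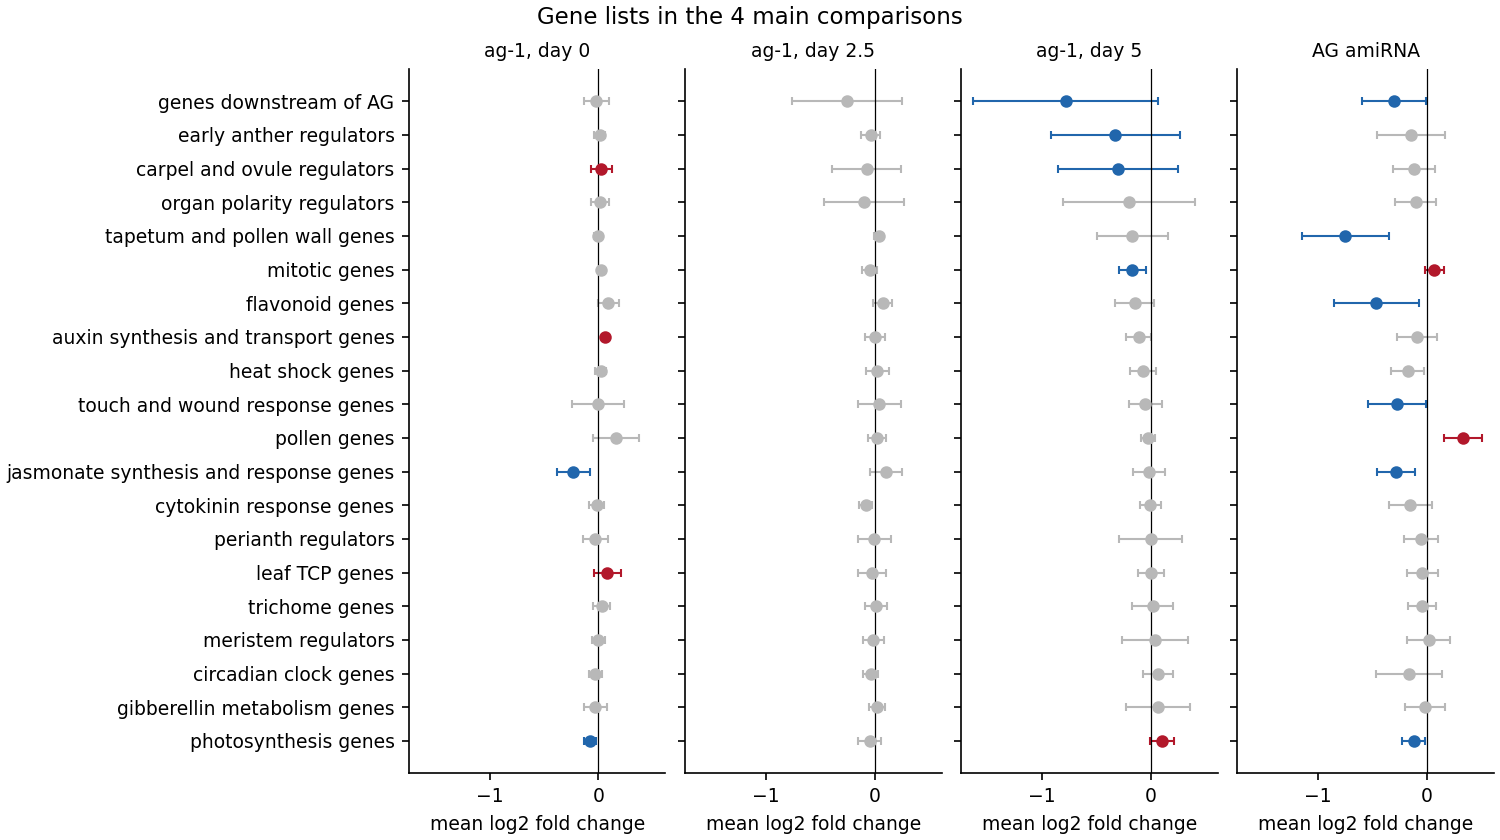
Mean log2 fold change (horizontal axis, log2 units, bars the SD over the genes of a list) of 20 gene lists in the 3 ag-1 comparisons and with the AG amiRNA. Red and blue mark lists with an adjusted p under 0.05 at the preset correlation, none of which holds with an estimated correlation. With median centring the day 0 auxin and carpel means, the day 5 photosynthesis mean and the amiRNA mitotic mean turn negative. The medians of all genes in these comparisons are then -0.09, -0.31 and -0.28.

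Both ways of lowering AG were then compared gene by gene. At day 5 and with the amiRNA 17 genes were called in both, where 2.49 are expected by chance (Fisher exact p = 5.44e-10), and 14 of them fell in both. Among these 14 are CRC, SPL, SUP, HEC2, WOX12, LAP3, ENDO3, BAM5 and OFP1, an ovate family gene, at -0.67 in ag-1 and -0.47 with the amiRNA. SEP3 and ATG8F, an autophagy gene in the span around AG, rose in both, with ag-1 values of 0.31 and 0.79 and amiRNA values of 0.55 and 0.35. The SEP3 value in ag-1 turned negative with median centring, where the median of all genes was -0.31. CIPK12, a kinase gene in the span, was lower in ag-1 at -0.66 and higher with the amiRNA at 0.40. REM22, the gene with the strongest fall at day 5, had a value of -0.01 with the amiRNA (SE 0.09, adjusted p = 0.962).

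Outside the span around AG, 14 of 135 genes called at day 5 were called with the amiRNA (Fisher exact p = 9.66e-10), and 111 of the 135 had the same sign in both. Across 17671 genes measured in both the log2 changes had r = 0.162, with genes not independent replicates. The same correlation was -0.13 for day 0 and 0.042 for day 2.5, with 1 and 3 shared calls. The number of shared calls was 3 without replicate 1 or 3 of the amiRNA, 38 and 52 without replicates 2 and 4, and 27 and 11 without replicates 1 and 3 of day 5.

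**Figure D4:**
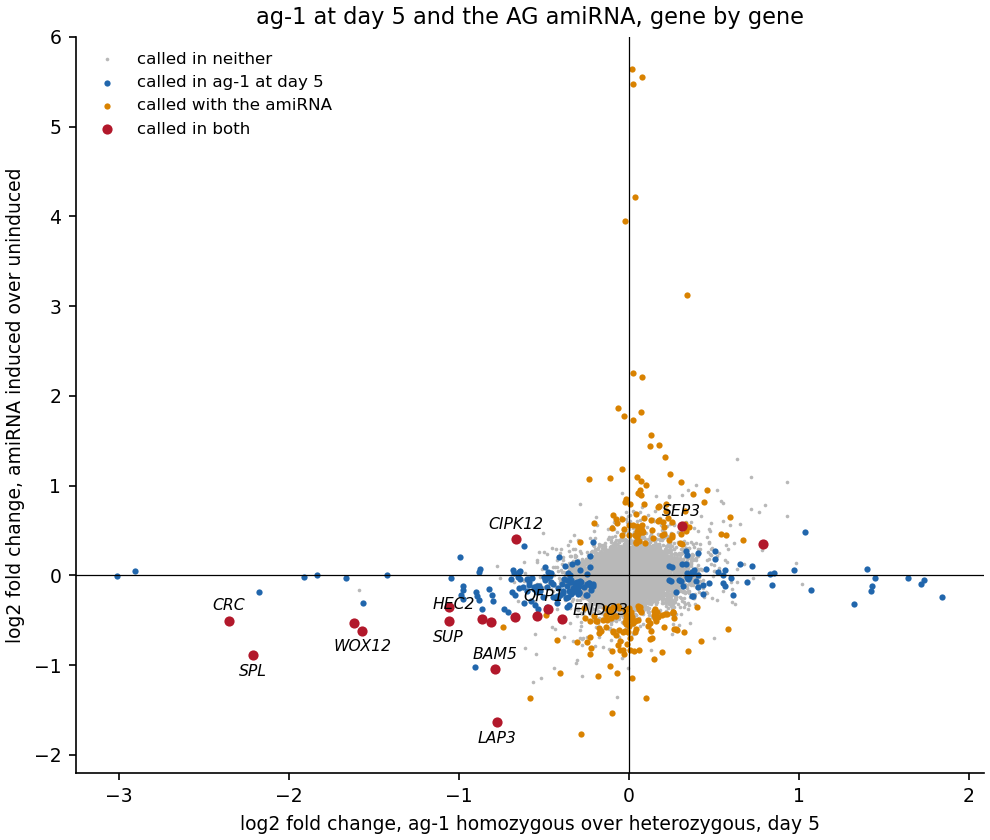
Log2 fold change of each gene in ag-1 at day 5 (horizontal axis, log2 units) against that with the AG amiRNA (vertical axis, log2 units), with the 17 genes called in both in red. CRC, SPL, WOX12, SUP, HEC2 and LAP3 lie below 0 on both axes, SEP3 above 0 on both (below 0 at day 5 with median centring, as is the median of all genes), and the strongest amiRNA rises lie near 0 in ag-1.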

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

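The tests of the bound on the rises at day 0 alone, and of the same bound at day 5 under other settings, were chosen only after the result was seen.

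The differences between days were each tested, and the values of the genes called are these, many of which lose the call under other settings. The limit set by low signals at day 0 holds here too. From day 0 to day 2.5 the ag-1 effect moved by -1.14 for REM22 (from -0.36 to -1.50) and by -0.59 for ENDO3 (from 0.13 to -0.46). From day 0 to day 5 it moved by -2.65 for REM22, -2.19 for SPL (from -0.02 to -2.21), -1.54 for WOX12 (from -0.02 to -1.57), -1.05 for IDD12 (from 0.07 to -0.98) and -1.04 for AGO5 (from 0.07 to -0.97). In the other direction it moved by 0.91 for GA3OX3 (from -0.06 to 0.85), 0.79 for MT2A (from -0.23 to 0.56), 0.73 for GA2OX4 (from -0.08 to 0.65) and 0.58 for P5CS1 (from -0.24 to 0.34). From day 2.5 to day 5 it moved by -1.51 for REM22 and -1.25 for WOX12, in a comparison where other splits of the arrays gave as many genes or more.

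The first pattern is the group of 41 genes called at day 0 around AG. Loss of AG function as their cause is argued against by the amiRNA, which lowered AG but moved these genes, turned to their ag-1 direction, by a median of -0.0124 (95% bootstrap interval -0.0765 to 0.0543, 32 genes measured, AG among them), against 0.735 at day 0. The amiRNA lowered AG only in part (-1.77) and in inflorescences with flowers. An effect confined to day 0 tissue is argued against by day 5, where all 41 genes had the same direction and 31 were called. An effect of a fuller loss of AG, one not seen in whole inflorescences, or one on the genes not measured stays open. With the amiRNA 2.97% of the tested span genes were called, against 1.27% outside. A variant carried with ag-1 that acts on each chromosome's own copy allows a homozygote at most a log2 rise of 1, and over the 3 days 8 of 60 called rises of the span lay above 1 by more than 2 SE, all 8 at day 5 and 4 of them in genes also called at day 0. At day 5 that count was 0 with median centring (7 of the 8 genes stayed above 1). With that day's arrays alone it was 1, as only 1 rise was called, but 7 of the 8 genes stayed above the bound. It was 3 without replicate 4 (all 8 genes stayed above 1) and 6 to 14 in the other alternatives. The count thus speaks against such a variant as the whole account there with loess but leaves it open. At day 0 alone 0 of 15 called rises did so (3 lay above 1, the highest at 1.24), so a linked variant may account for the day 0 values and stays open there as a hypothesis. A sequence difference under the probes cannot be told apart from these, because 8 span genes with more than 1 probe are too few. Their 2 brightest probes differed by a median of 0.15 at day 0, against 0.0698 at day 5 in 50 genes called outside on that day. The difference was 0.0799 (one-sided permutation p = 0.085, 100000 permutations). The 2 sets differ in day, and the span set holds AG. Sizes of change differ too, as the median absolute log2 change of all called genes was 0.81 at day 0 and 0.50 at day 5.

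The second pattern is the group of 7 genes that rose by more than 3 on the log2 scale with the amiRNA, MIR319a, NAC1, STP1, EXPA2, AT3G05640 (4.22), AT4G14819 (5.48) and AT5G26290 (5.55), the last 3 outside the naming rule and named after their values were seen. A lasting response to dexamethasone is argued against by the heterozygote, where 6 of the 7 were measured and had a median change of -0.0209 from day 0 to day 2.5 (95% bootstrap interval -0.214 to 0.163), while a short-lived response or one of whole inflorescences stays open. More active miR319 predicts lower TCP targets, and this cannot be told from 5 measured targets with a median of 0.00735 (95% bootstrap interval -0.318 to 0.0641), among them TCP3 at -0.32 (adjusted p = 0.0651). Artificial microRNAs are often built into the MIR319a precursor, so the MIR319a probe might also read the transgene itself, which was not tested for want of probe sequences. Whether lower AG itself raises these genes stays open, as 6 of them had day 5 values in ag-1 of at most 0.34 and EXPA2 was not measured there.

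In 11 of 123 groups of 4 arrays a single array stood apart, where chance gives about 1 in 20. On replicate 4 of day 0 SBP2 had a ratio of -0.37 against -1.15 to -1.08 on the others. MYC4 had 0.70 on replicate 4 of day 2.5 against 0.38 to 0.41. At day 5 PNF had 0.60 on replicate 4 against 0.24 to 0.27, DI21 had 3.42 on the same array against 1.14 or more, and SHM4 had 0.52 on replicate 2 against 1.19 to 1.31. With the amiRNA, on replicate 2, GSTF12 had -1.95 against -0.83 to -0.77 and UF3GT had -2.39 against -1.05 to -0.99. The median red background was 34.5 on replicate 1 of day 2.5 against 35 on the other arrays and 30.5 on replicate 2 of the amiRNA against 30. On replicate 4 of day 0 65.9% of probes were well above background in the homozygous channel against 63.2% to 63.4%. On replicate 4 of the amiRNA 206 spots were marked as outliers against 32 to 54.

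Probes outside annotated genes gave few calls. Of 1020 intergenic probes 1 was called at day 0 (-1.83), 1 at day 2.5 (-1.34) and 2 at day 5 (lowest -0.90), with 1 on chromosome 4 at each day, and of 477 in the amiRNA fit 1 was called, at 0.73, also on chromosome 4. Of 130 predicted-gene probes 1 was called at day 0 (-0.29).

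Other assignments of sign to the 4 arrays of a group were tried. At day 0 the real pattern called 41 genes and the highest of the other patterns 0, at day 2.5 38 against 0, at day 5 212 against 0 and with the amiRNA 237 against 1; 8 patterns for each day, and 7 that could be fitted for the amiRNA, are too few for a share under 0.05. Among 35 splits of 8 arrays, only the real one reached its count from day 0 to day 5 (26 genes against at most 0). That count was 23 with slide as a fixed block, though 2 or 3 without any one replicate of day 0. The real split also stood alone for the heterozygous levels at day 2.5 (2460 against 0) and day 5 (4777 against 0). Splits that mix days carry day effects into the residual and so can call fewer genes, and they ignore the slides. They therefore do not exclude chance. For the difference from day 0 to day 2.5 the real split gave 2 genes and the others at most 0, but all these splits ignore the slides, and here 0 genes were called with slide as a fixed block, on slide 2 alone, with no dye term, with no background subtraction and without each of 5 single replicates, so the difference is left open. For the difference from day 2.5 to day 5 chance cannot be excluded either, since 4 splits gave 2 or more genes. The highest other split gave 1012, and what sets it apart was not tested.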

How the results depend on the processing

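The alternatives with slide as a fixed block, single slides, without the genes of the span around AG, all alternatives of the shared calls, and the gene lists without single replicates or with slide blocked were chosen only after the data were seen.

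Of 122 named calls 42 were kept under every alternative run for them, and of the main results under their alternatives 135 stayed the same, 92 moved and 1 reversed. Where they moved the cause was not tested. The filter on both channels of every array and other ways to form the heterozygous level moved none. Aquantile scaling moved none either, but it scales intensities and leaves the ratio of each probe as it was. It could change the ratio comparisons only through the probe chosen for a locus. That it moved none is therefore no sign of stability, though it is counted among the alternatives above. Between 55.0% and 66.4% of probes were well above background, and whether this share bears on the moves was not tested.

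With scanner processed signals the differences from day 0 to 2.5, 0 to 5 and 2.5 to 5 gave 1, 41 and 7 genes, the amiRNA 155 and the shared calls 10. With no background subtraction day 2.5 gave 62, day 5 gave 368 and the differences 0, 59 and 20. Median centring in place of loess gave medians of all genes of -0.09, 0.03, -0.31 and -0.28 in the 4 main comparisons and called 13, 11 and 101 genes at day 0, 2.5 and 5, of which 0, 0 and 2 rose, differences of 0, 6 and 1, and 124 for the amiRNA, of which 24 rose. It kept 45 of 102 named calls, and at day 5 the sign reversed for SEP3 (-0.12), STM (-0.04) and PNF (-0.03), though all lie above the median of all genes there. The share of rises at day 5 also moved with scanner processed signals (135 of 308) and the deposited table (144 of 307), which gave 1 gene from day 0 to 2.5 and 7 from day 2.5 to 5. With no filter on dim probes the amiRNA gave 156 and the shared calls 11, and with the mean over probes the first difference gave 1.

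With no dye term day 0 gave 23, day 5 gave 135 and the first difference 0. Array weights gave 251, 69 and 733 genes for the 3 days and 4, 710 and 11 for the differences. Slide as a random block gave 4 genes from day 2.5 to 5 and could not be estimated for the amiRNA, which has 3 arrays on one slide and 1 on the other. The slide correlation in ag-1 was -0.065. Fits on only that day's arrays gave 95, 24 and 13, and all 16 arrays in 1 fit gave 1098 for the amiRNA. Replicate numbers do not pair arrays of different days, since 3 of 12 same-number pairs had r above 0.1 after the dye term (-0.529 to 0.357) and 2 arrays correlated best with their own number. With replicate as a block the first difference gave 1 and the second 17. Slide as a fixed block gave 15, 1 and 85 for the days, 0 from day 0 to 2.5, 1 from day 2.5 to 5, 899 and 2516 for the heterozygous levels, and kept 49 of 93 named calls. Slide 2 alone gave 0 for the first difference, and slide 4 alone gave 11 for the second and 656 for the heterozygous level at day 5. Without the span around AG 0, 3 and 103 genes were called at the 3 days by limma. Day 0 or 2.5 in place of day 5 gave a correlation with the amiRNA of -0.13, a reversal, or 0.042, with 1 and 3 shared calls, and the estimated correlation called 0 lists (camera, 6 at an unadjusted p under 0.05).

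Without 1 replicate the counts ranged from 12 to 34 at day 0, 21 to 34 at day 2.5, 86 to 385 at day 5, 0 to 2, 2 to 67 and 2 to 18 for the differences, 51 to 2531 for the amiRNA, 1587 to 2146 for the heterozygous level at day 2.5 and 3 to 52 for the shared calls. SHP2 reversed with the amiRNA, from a value of -0.34 without replicate 2 to 0.23 without replicate 4. The touch and wound list reversed at day 0 without replicate 2 (adjusted p = 1.64e-05, over a range of 1.64e-05 to 0.976 for its alternatives) and stood at 0.955 and 0.00155 without replicates 1 and 4. It also reversed at day 2.5 with slide as a fixed block (adjusted p = 0.0123, over a range of 0.0123 to 0.974).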

Other observations

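No test in this part was chosen after its result was seen. The values of the first paragraphs are of the heterozygous channel in ag-1 siblings, where stage and dexamethasone treatment move together.

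JAG, a zinc finger gene of lateral organ growth, was higher at day 2.5 than at day 0 by 4.05 (SE 0.13, adjusted p = 2.54e-08) and at day 5 by 4.34 (adjusted p = 1.01e-08). ENDO3 was higher by 3.99 and 4.44 (SE 0.16, adjusted p = 8.89e-08 and 1.98e-08), SUP by 2.68 and 2.85 (SE 0.16, adjusted p = 9.45e-07 and 3.27e-07) and PI by 2.41 on both days (SE 0.11, adjusted p = 1.01e-07 and 6.06e-08). AP2, a gene of sepal and petal identity, was higher by 2.06 and 2.00 (SE 0.13, adjusted p = 2.13e-06 and 1.21e-06). SPL and CRC had values of 0.21 (SE 0.22, adjusted p = 0.597) and 0.36 (SE 0.28, adjusted p = 0.475) at day 2.5 and rose by 2.77 (adjusted p = 4.34e-06) and 2.89 (adjusted p = 2.23e-05) at day 5.

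No gene list was tested on these levels. WUS had values of -0.54 at day 2.5 (SE 0.25, adjusted p = 0.197) and -1.79 at day 5 (adjusted p = 0.000298), STM of -0.65 and -1.57 (SE 0.11, adjusted p = 0.00288 and 2.27e-06) and PNF of -0.70 and -1.80 (SE 0.11, adjusted p = 0.00214 and 9.71e-07). GA3OX3, which was higher in ag-1 at day 5, had a value of -0.42 at day 2.5 (SE 0.17, adjusted p = 0.143) and fell by 1.97 on the log2 scale at day 5 (adjusted p = 8.58e-06). Of the carpel genes VDD rose by 1.80 and 3.03 (SE 0.21, adjusted p = 0.000191 and 1.67e-06), and HEC2 had values of -0.04 (adjusted p = 0.922) and 1.04 (SE 0.19, adjusted p = 0.00185).

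Some named genes have several probes that differ. The 3 probes of MYC4 went from -0.13 to 0.47 at day 2.5. Probes of 1 gene had opposite signs in 9 of 23 named genes with several probes at day 0, 10 of 25 at day 2.5, 6 of 31 at day 5 and 3 of 26 with the amiRNA.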
